A study of Homo sapiens with 12 samples.

How the data were processed

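RNA was measured in 12 libraries from HEK293 cells, an established human embryonic kidney line, in 6 groups of 2. Per the labels' protocols, lines stably expressed FLAG/HA-tagged RPL12 as wild type (WT), as S38A (serine replaced by alanine, which cannot be phosphorylated) or as S38D (serine replaced by aspartate, used as a mimic of phosphorylation). Each input library came from an aliquot of a pooled 80S fraction of a sucrose gradient, and each IP library from anti-FLAG immunoprecipitation of the rest of that fraction. Per the labels, polyadenylated RNA was sequenced and ERCC spike-in RNA was added to the input RNA in equal amounts. The spike-in amount used for the IP RNA is not given in the sources used here. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

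The authors deposited raw read counts per gene, 1 table per library, with 57820 Ensembl gene identifiers and 92 ERCC sequences. Per the submitters' processing notes, bcl2fastq 2.16.0.10, STAR 2.4.2a and DESeq2 were used with the hg19 genome build. The read counter, its handling of strand and multiply mapped reads, and the annotation release are not given in the sources used here, so values of overlapping, antisense and near-identical genes are uncertain. ERCC counts were kept out of library sizes and gene tests, except in the alternative with spike-in scaling of the inputs.

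The files do not pair identifiers with names. The reference table held 59792 genes, of which 0 carried an Ensembl identifier, so 0 identifiers were matched to a symbol. Genes are given by identifier, at most 2 higher and 2 lower per comparison. For the same reason the 20 gene lists fixed by symbol matched no identifier, and the tagged gene was not analysed here. The rule for named genes, set before the data were examined along with the groups, tests and most alternatives, asked for adjusted p under 0.05, a symbol, mean CPM of at least 5 and no overlap between the libraries of the 2 sides, ranked by fold change. The symbol was dropped from the rule. Where fewer than 5 genes qualified, those of lowest p were taken and are said not to have passed.

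Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr on group with a minimum count of 10, TMM scaling, and glmQLFit with glmQLFTest, with Benjamini-Hochberg adjustment within each of 10 comparisons and calls at adjusted p under 0.05. IP and input were compared in 1 fit of all 12 libraries (16920 genes, biological coefficient of variation 17.4%). Differences between lines in IP over input were interaction contrasts in that fit. Inputs were compared in a fit of the 6 input libraries (16728 genes, 15.7%). The standard error of a log2 fold change was its size divided by the square root of the quasi-likelihood F. Log2 CPM used a prior count of 2.

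Cell cycle lists were built from the human marker pairs in scran 1.30.0, keeping genes in at least 20 pairs of a phase that were the higher partner in a share of at least 0.8 of them and that fell in 1 phase list. They were chosen after seeing the data. Of these, 239 G1, 251 S and 208 G2M genes were tested. The lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the lists within a comparison.

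Same-numbered input and IP libraries of a line come from the same fraction per the labels, and their deviations from the group means correlated across genes at 0.28 in WT, 0.64 in S38A and 0.54 in S38D. These numbers therefore pair the libraries, and a fit with the fraction as a replicate block was an alternative. Chi-square per degree of freedom between replicates was 5.39 to 16.0, so no replicate pair agreed within sampling noise.

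Alternatives were RLE size factors, total counts, DESeq2 1.42.0, voom with sample quality weights, no filter, mean CPM of at least 10, the replicate block, other sets of libraries in the fit, spike-in scaling of the inputs and omission of each library in turn. Thinning to equal depth, repeated in 10 further draws, and the block without the first WT fraction were added after seeing the data. Confidence intervals of spike-in shares are exact Clopper-Pearson 95% intervals and cover counting error only.

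The fits were tested on simulated counts with known changes, drawn independently for each library with no effect shared within a fraction. For IP versus input over the 3 lines, 98.0% of 4-fold and 72.9% of 2-fold changes were recovered among 16668 genes. For IP versus input in WT, the shares were 80.6% and 29.6% among 16634 genes. For S38A versus WT in IP over input, they were 72.7% and 12.0% among 16670 genes. For input S38D versus WT, they were 74.7% and 41.8% among 16545 genes. Unchanged genes were also called: 7, 11, 8 and 12, in the order of these comparisons. For S38A versus WT the 8 false calls stood beside 72 recovered 4-fold and 12 recovered 2-fold changes. With the fraction as a block 14 false calls stood beside 69 and 11.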

Results

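Polyadenylated RNA of 80S fractions was compared with RNA from anti-FLAG IP of tagged RPL12 in the same fractions. RPL12 is a protein of the large ribosomal subunit, and the HEK293 lines expressed its WT, S38A or S38D form. Each of the 6 groups held 2 libraries. Input libraries held 7434431 to 8723130 gene counts. The IP libraries held 3186164 and 5048911 in WT, 6150315 and 7430881 in S38A, and 4390785 and 3695441 in S38D. Replicates correlated across genes at 0.957 to 0.979 in log2 CPM, and genes are not independent replicates. The first principal component, with 36.05% of the variance, placed all 6 IP libraries on one side of the 6 inputs.

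ERCC spike-in RNA took a larger share of counts in IP than in input libraries. The share was 3.43% ± 1.65 (SD, n = 6) in IP and 0.305% ± 0.127 (SD, n = 6) in input. The ratio of geometric means was 11.03-fold, and the share was higher in IP in 6 of 6 fractions (two-sided exact permutation within fractions, p = 0.031, the smallest that 64 assignments can give). Within the IP libraries the share was 4.00% ± 2.02 in WT, 1.79% ± 0.502 in S38A and 4.49% ± 0.982 in S38D (SD, n = 2 each). Counting error was small beside this spread, with a 95% Clopper-Pearson interval of 5.41% to 5.45% in the first WT library and 2.56% to 2.58% in the second. Between the lines an exact permutation test gave p = 0.267 over the 15 partitions of the 6 IP libraries, a design that cannot go below 0.0667.

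**Figure D1:**
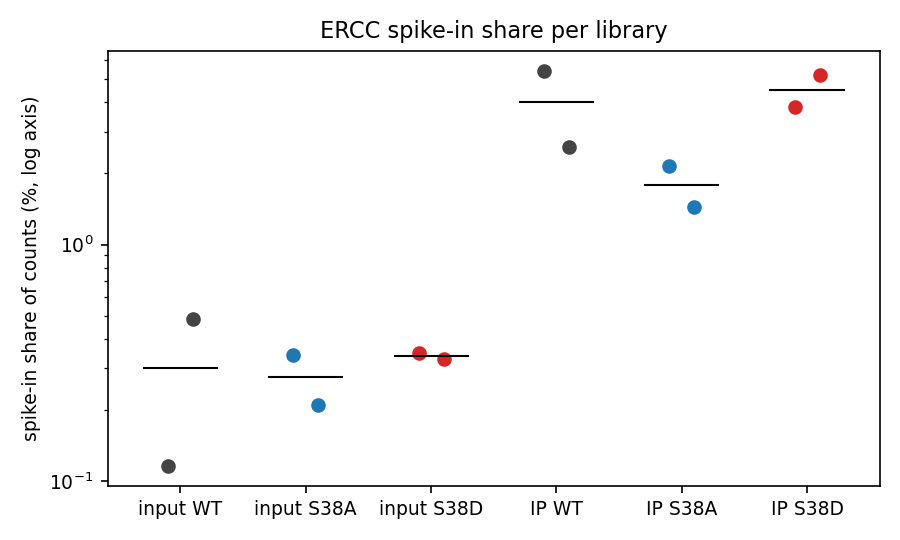
Spike-in share of all counts (%, log axis) in each library by group, with points for libraries, coloured by line, and a horizontal bar for the mean of 2. The IP libraries lie between 1.44% and 5.43% and the input libraries between 0.116% and 0.484%.

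The first comparison asked which RNAs differed between tagged-RPL12 IP and 80S input over the 3 lines. No library is an IP from cells without tagged RPL12. RNA bound without the tag, and library differences that go with IP, therefore cannot be told apart from recovery through RPL12. Of 16920 genes, 2690 were higher and 2688 lower in IP (edgeR quasi-likelihood test, adjusted p under 0.05). Changes were mostly moderate, with 325 called genes at least 2-fold higher and 296 at least 2-fold lower. ENSG00000159450.8 rose by 2.51 on the log2 scale (SE 0.37, adjusted p = 0.00049) and ENSG00000099866.10 by 2.41 (SE 0.34, adjusted p = 0.00043). ENSG00000261366.1 changed by -1.71 (SE 0.22, adjusted p = 0.00027) and ENSG00000169570.5 by -1.64 (SE 0.18, adjusted p = 0.00013). The rule for naming required that each of these 4 genes moved in its direction in 6 of 6 fractions. The split of calls depended on scaling: with total counts 1298 genes were higher and 5251 lower, and the median of all genes moved from -0.04 to -0.25.

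Abundant transcripts made up most of the genes higher in IP. Abundance was averaged over IP and input libraries, and changes are easier to call at high counts. Numbers of calls are therefore not directly comparable between quartiles. In the abundance quartile with the highest CPM, 1579 were higher and 535 lower, and the median log2 change was 0.17. In the quartile with the lowest, 183 were higher and 304 lower, with a median of -0.16. With total counts 817 were higher and 1150 lower in the highest quartile, and 109 and 659 in the lowest. The medians were then -0.04 and -0.37. The sign of the change of the most abundant quartile thus depended on scaling, while the order of the quartiles was the same.

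**Figure D2:**
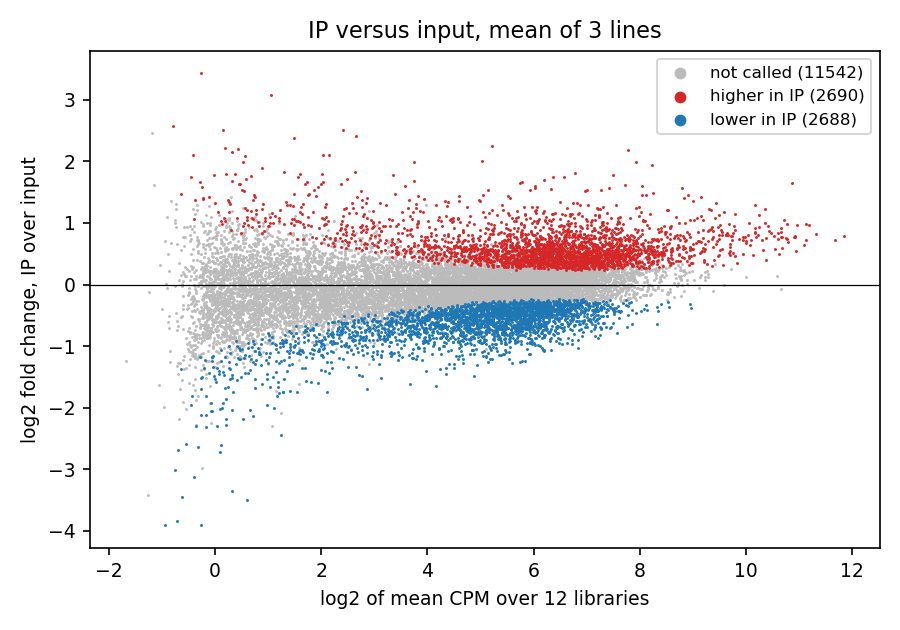
Log2 fold change of IP over input, averaged over the 3 lines, against log2 mean CPM for each tested gene. Red points are the 2690 genes higher in IP and blue points the 2688 lower, with most red points at high CPM.

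Among the cell cycle lists, G1 markers were shifted upward in IP, with 67 of 239 members higher and 36 lower (73 and 40 adjusted over the list alone). Their median log2 change was 0.12, and camera gave adjusted p = 0.0145 with the preset correlation and adjusted p = 0.52 with an estimated correlation. With total counts 32 members were higher and 70 lower. The median was then -0.10, above the -0.25 of all genes, and the call was lost there (camera adjusted p = 0.17) and with mean CPM of at least 10 (0.10). Of 251 S markers, 61 were higher and 51 lower (camera adjusted p = 0.13). Of 208 G2M markers, 52 were higher and 29 lower (camera adjusted p = 0.13). With total counts 37 S markers were higher and 87 lower, and 27 G2M markers were higher and 62 lower. No list call in any of the 10 comparisons held with an estimated correlation.

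The next comparison took each line separately. In WT, 976 genes were higher and 927 lower in IP. ENSG00000159450.8 rose by 3.67 (SE 0.67, edgeR adjusted p = 0.0089) and ENSG00000138778.7 by 3.15 (SE 0.46, adjusted p = 0.0063), while ENSG00000030419.12 changed by -2.22 (SE 0.47, adjusted p = 0.015) and ENSG00000267152.1 by -2.11 (SE 0.32, adjusted p = 0.0070). ENSG00000138778.7 averaged 78.0 ± 64.4 CPM in WT IP and 8.6 ± 0.4 in WT input (SD, n = 2), so its IP replicates lay far apart. Without the first WT IP library the changes of these 4 genes were 2.57, 1.94, -1.84 and -1.93, and ENSG00000159450.8 and ENSG00000030419.12 did not pass (edgeR adjusted p = 0.068 and 0.093). Without the second they were 4.36, 3.84, -3.04 and -2.36. The same 2 genes did not pass without the first WT input (adjusted p = 0.063 each), nor ENSG00000030419.12 in voom (0.10). The number of genes called in WT was 0 without the second input library, 212 without the first, 344 without the first IP library and 2869 without the second. It was 4818 with the fraction as a block, which held 1902 of the 1903 calls, and 0 when only the 4 WT libraries were fitted. With total counts 484 genes were higher and 2444 lower.

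In S38D, 530 genes were higher and 294 lower in IP. ENSG00000099866.10 rose by 2.76 (SE 0.60, edgeR adjusted p = 0.029) and ENSG00000132467.2 by 2.47 (SE 0.33, adjusted p = 0.020), and ENSG00000261366.1 changed by -1.98 (SE 0.39, adjusted p = 0.025) and ENSG00000169570.5 by -1.68 (SE 0.31, adjusted p = 0.023). ENSG00000132467.2 stood at 434 ± 112 CPM in S38D IP and 78.2 ± 5.9 in S38D input (SD, n = 2). Without the first IP library of S38D 4 genes were called, of those named here ENSG00000132467.2 alone (adjusted p = 0.041), and without the second, or without either S38D input, 0 were. Without the first or second WT input 406 and 395 genes were called, and without the first or second WT IP library 1809 and 1787. With the fraction as a block 3379 genes were called, all 824 among them. With only the 4 S38D libraries ENSG00000099866.10 did not pass (edgeR adjusted p = 0.051). With total counts 242 genes were higher and 1380 lower.

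In S38A, 0 genes passed in IP versus input, with 2575 at unadjusted p under 0.05 against 846 expected by chance and a lowest adjusted p of 0.12 (edgeR). The genes of lowest p, ENSG00000139133.2 at -1.38 (SE 0.20) and ENSG00000101966.8 at -0.93 (SE 0.14), did not pass, and both passed with the fraction as a block (adjusted p = 0.0069 each). DESeq2 called 446 genes, voom 0, and the edgeR fit with the fraction as a block 2079, of which 1001 were higher and 1078 lower. Without the first or second WT IP library edgeR called 139 and 100. Of the genes called higher in WT, 99.5% had a positive change in S38A, and of those called lower, 99.4% a negative one. Between WT and S38D, which share no libraries, 421 genes were called higher in both against 30.6 for independent lists, and 245 lower in both against 16.1. Both lists come from 1 fit that shares its estimates of spread, and the independent numbers take every gene as equally detectable. The excess therefore is not a measure of shared changes alone.

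G1 markers were shifted upward in WT (median 0.10, camera adjusted p = 0.043; adjusted p = 0.48 with an estimated correlation) and in S38D (median 0.18, camera adjusted p = 0.0040; adjusted p = 0.43 with an estimated correlation). With total counts these medians were -0.16 and -0.08, above the -0.30 and -0.31 of all genes, and neither call passed (camera adjusted p = 0.23 and 0.084). The WT call was also lost with the fraction as a block (adjusted p = 0.061), with no filter (0.29), with mean CPM of at least 10 (0.14), with thinned counts (0.075) and with the block without the first WT fraction (0.71). No list passed in S38A.

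**Figure D3:**
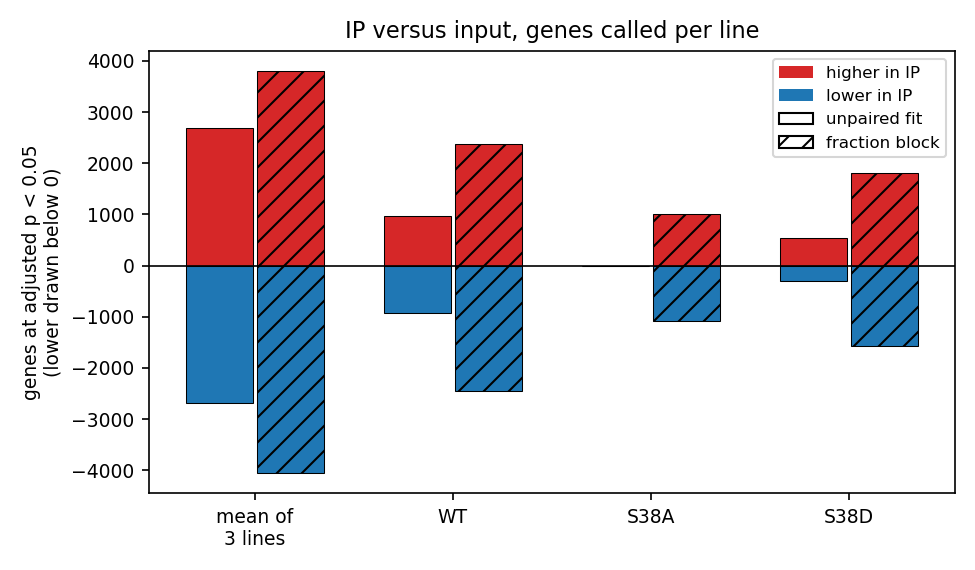
Number of genes called between IP and input (adjusted p under 0.05), higher in IP above 0 and lower drawn below 0, for the mean of 3 lines and for each line. Plain bars are the fit without pairing and hatched bars the fit with the fraction as a block, in which S38A has 1001 genes higher and 1078 lower.

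Whether recovery differed between lines was tested with interaction contrasts. For S38A versus WT 0 genes passed in edgeR, with 393 at unadjusted p under 0.05. For S38D versus WT 0 passed, with 134, and for S38D versus S38A 0 passed, with 109, where chance gives 846. This fit leaves out the pairing of input and IP libraries. With fewer small p-values than chance gives, its 0 calls are weak evidence that the lines do not differ. DESeq2 and voom also called 0 in each. The fit with the fraction as a block called 0 in each as well, with 1177 genes at unadjusted p under 0.05 for S38A versus WT, above the number expected by chance, and 460 and 578 for the other contrasts, below it. Few 2-fold differences would be detectable in a fit without a block, since the simulated S38A versus WT contrast recovered 12.0% of them. The simulated libraries shared no fraction effect, unlike the real ones, so the power in these data may differ. With no filter on low counts 39 genes passed for S38A versus WT, all lower in S38A. Without the second WT IP library 293 genes passed for S38A versus WT, of which 288 were lower in S38A.

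G2M markers were lower in S38A than in WT in IP over input (median -0.07, camera adjusted p = 0.0068; adjusted p = 0.50 with an estimated correlation). With total counts that median was 0.07, below the 0.19 of all genes, and the call was lost with no filter (camera adjusted p = 0.53). A fit of the IP libraries alone compares IP levels between lines without the inputs, and there the list did not pass (camera adjusted p = 0.74). With the block without the first WT fraction the median was 0.07 and the call was lost (adjusted p = 0.43). G1 and G2M markers were higher in S38D than in S38A (medians 0.07 and 0.04, camera adjusted p = 0.0093 and 0.031; adjusted p = 0.44 for both with an estimated correlation), with medians of -0.07 and -0.11 with total counts, above the -0.16 of all genes. With total counts neither call passed (adjusted p = 0.18 and 0.20), nor with no filter (0.088 and 0.13). The G2M call was also lost with the fraction as a block (camera adjusted p = 0.073), with mean CPM of at least 10 (0.065) and with thinned counts (0.12). Between the IP libraries alone, without the inputs, the G2M list did not pass (camera adjusted p = 0.86). In the filtered fit without a block 0 members of these lists passed singly. With no filter 5 G2M members were lower in S38A than in WT, and with the block without the first WT fraction 12 G1 and 11 G2M members were higher in S38D than in S38A.

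The inputs were compared to ask whether the 80S-associated RNA itself differed between lines. Form and line coincide in these samples, so a difference between lines need not come from the RPL12 form. One identifier, ENSG00000082805.15, was higher in S38D. It stood at 403 ± 45.2 CPM in S38D input, 75.7 ± 20.4 in WT and 89.3 ± 9.8 in S38A (SD, n = 2 each). The increase was 5.37-fold over WT (log2 2.43, SE 0.20, edgeR adjusted p = 0.0074) and 4.50-fold over S38A (log2 2.17, SE 0.20, adjusted p = 0.018), and both comparisons share the S38D libraries. In IP libraries it stood at 496 ± 64.0 CPM in S38D, 79.7 ± 36.1 in WT and 78.7 ± 9.6 in S38A, and the difference in IP over input between S38D and WT did not pass (log2 0.25, SE 0.38, adjusted p = 1.00). The call against WT was lost without the second WT input (adjusted p = 0.072) and without the first or second S38A input (0.061 and 0.058). The call against S38A was lost without the first or second S38A input (0.19 and 0.18). With spike-in scaling the changes were 1.43 and 1.74 and neither passed (adjusted p = 0.71 and 1.00). The spike-in shares of the WT inputs lay far apart (0.116% and 0.484%), and that fit shares its estimate of spread over all inputs.

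**Figure D4:**
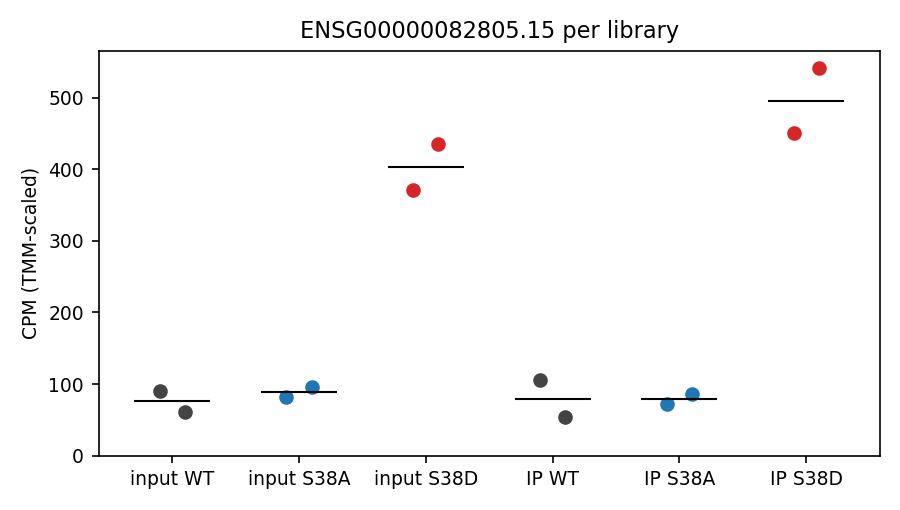
TMM-scaled CPM of ENSG00000082805.15 in each library by group, with points for libraries, coloured by line, and a horizontal bar for the mean of 2. The S38D groups average 403 CPM in input and 496 in IP, above all libraries of the other lines.

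Between S38A and WT inputs 0 genes passed in edgeR, with 2566 at unadjusted p under 0.05 against 836 expected by chance and a lowest adjusted p of 0.17. With no filter on low counts edgeR called 924 genes, 586 higher and 338 lower in S38A. DESeq2 called 398 genes and voom 0, and edgeR called 495 without the first S38A input, 2 without the second, 11 without the first WT input and 7 without the second S38D input. ENSG00000133858.11 at 1.51 (SE 0.19) and ENSG00000233922.1 at -1.48 (SE 0.21) were among the genes of lowest p and did not pass. Lists of S and G2M markers were higher in S38A input (median 0.08 each, camera adjusted p = 0.013 each; adjusted p = 0.47 for both with an estimated correlation). With spike-in scaling their medians turned to -0.31 and -0.32, above the -0.44 of all genes. Against WT, S38D inputs had 555 genes at unadjusted p under 0.05, and against S38A 630. Without the first S38D input 14 and 9 genes passed in these comparisons, and without the first WT input 10 passed against WT.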

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

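The cell cycle lists and the tests of spike-in shares were chosen after the data had been seen. In IP over input, 3 list shifts differed between lines by an interaction contrast with a preset correlation: G2M markers in S38A versus WT (median log2 change -0.0728), G1 markers in S38D versus S38A (0.0679) and G2M markers in S38D versus S38A (0.0351). None held with an estimated correlation or with fry. Spike-in RNA, used in gene comparisons only for an alternative scaling of the inputs, averaged 3.43% of the counts in IP libraries against 0.305% in inputs.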

How the results depend on the processing

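Thinning to equal depth, the replicate block without the first WT fraction and all list tests were chosen after the result was seen; the other alternatives were planned. Of single-gene values 588 kept their side of the threshold, 41 newly passed and 38 no longer did. For list tests the numbers were 202, 8 and 19, and 2 reversed. Counts of calls stayed within 1.5 times in 137 cases, mostly 0 against 0, and moved in 62. The cause was not tested. For IP versus input over the 3 lines the count was 4007 to 5770 with 1 library left out, and 9171 with the replicate block without the first WT fraction. In WT, 1903 genes became 2928 with total counts, 597 with voom, 4818 with the replicate block, 0 with only the 4 WT libraries, 5087 with the block without the first WT fraction, and 0 to 2869 with 1 library left out. In S38A, 0 became 7 with total counts, 399 with no filter, 446 with DESeq2, 2079 with the block, 6087 with the block without the first WT fraction, and 0 to 139 with 1 library left out (139 and 100 without the first and second WT IP library). In S38D, 824 became 1622 with total counts, 1555 with no filter, 1629 with DESeq2, 1847 with voom, 3379 with the block, 1530 with only the 4 S38D libraries, 6423 with the block without the first WT fraction, and 0 to 1809 with 1 library left out (406 and 395 without the first and second WT input, 1809 and 1787 without the first and second WT IP library). In IP over input, S38A versus WT gave 39 with no filter, 1 with the IP libraries alone (ENSG00000188211.4, log2 2.14), 29 with the block without the first WT fraction, and 0 to 293 with 1 library left out. S38D versus WT gave 1 with no filter (ENSG00000117724.8, log2 -1.43), 1 with the IP libraries alone, 59 with the block without the first WT fraction, and 0 to 0 with 1 library left out. S38D versus S38A gave 1 with the IP libraries alone, 405 with the block without the first WT fraction, and 0 to 0 with 1 library left out. The gene called in both S38D comparisons of IP libraries alone was ENSG00000082805.15. The other 2 identifiers were named after their values were seen. Input S38A versus WT gave 924 with no filter, 398 with DESeq2 and 0 to 495 with 1 library left out (11, 2 and 7 without the first WT, second S38A and second S38D input). Input S38D versus WT gave 87 with no filter, 11 with DESeq2, 0 with the replicate block, 0 with spike-in scaling and 0 to 14 with 1 library left out (10 without the first WT and 14 without the first S38D input). Input S38D versus S38A gave 49 with no filter, 2 with DESeq2 (ENSG00000082805.15 and ENSG00000117122.9), 0 with the block, 0 with spike-in scaling and 0 to 9 with 1 library left out (9 without the first S38D input). Replicate numbers of different lines share only a number, with deviations correlating at -0.07 to 0.22. With that number as a block, ENSG00000082805.15 had edgeR adjusted p = 0.058 against WT and 0.12 against S38A. For IP versus input over the 3 lines the block called 7860 genes, all 5378 among them, with 3804 higher and 4056 lower. It changed no other call of named genes and lists than given here or beside the results. Spike-in scaling moved the median of all genes in the inputs to -0.44 for S38A versus WT, -0.83 for S38D versus WT and -0.40 for S38D versus S38A. With the block without the first WT fraction, G2M markers in IP over input turned to 0.0732 for S38A versus WT, which did not pass (camera adjusted p = 0.43), and to 0.135 for S38D versus WT, which passed (0.0014). In that setting G1 and S markers also passed for S38D versus WT (0.13 and 0.11, camera adjusted p = 0.0032 and 0.0091) and S markers for S38D versus S38A (0.02, 0.048). With an estimated correlation the list calls of that setting had adjusted p = 0.12 to 0.20 in the 2 comparisons with S38D, and over all settings 0 of 231 list tests passed, with a lowest adjusted p of 0.12. The 20 lists fixed by symbol and omission of mitochondrially encoded and Pol III genes need gene names and were not run. A library left alone in its group was assumed to vary like the other groups.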

Other observations

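The tests of depth, of an equal change and of spike-in share were chosen after the result was seen. So were the separate shares for genes higher and lower in S38D, the matched genes and the place of the WT fraction. The test over all genes called between S38D and S38A and the count of splits were not. The setting that gave those called genes was itself chosen after the result was seen.

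IP and input differed beyond other splits of the libraries. With line as a term, the real split called 5951 genes, and of 100 splits 1, the real one, called as many. The highest other called 3065 and differed from the real split by the sides of 2 libraries. Among the 32 splits that part every pair of libraries from the same fraction, the highest other called 0. A chance split is argued against but not excluded, since the share of 0.031 is the smallest that these 32 splits can give. Replicates may be technical, so this holds for these libraries only.

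In the filtered edgeR fit of 12 libraries IP versus input called 1903 genes in WT, 824 in S38D and 0 in S38A (2575 at unadjusted p under 0.05), but voom called 597, 1847 and 0, fits of each line alone 0, 1530 and 0, the block without the first WT fraction 5087, 6423 and 6087, and DESeq2 446 in S38A, and the interaction contrasts of that edgeR fit called 0. The replicate block with all libraries called 4818 in WT, 3379 in S38D and 2079 in S38A, the same order of lines. A lower IP depth is argued against, since the shallower S38A IP library held 1.22 times the gene counts of the deeper WT one. In 10 draws thinned to equal depth WT also had at least 2.26 times as many calls as S38D (1734 to 1865 against 667 to 780). A separate first draw gave 1754 against 788. An equal change hidden by a larger spread is also argued against: the scale of the change shared between lines was 0.33 in S38A and 0.51 in WT on the log2 scale, a ratio of 0.644 that ranged from 0.567 to 0.750 over 8 choices of 1 fraction per line. A technical difference between IPs that goes with the spike-in share may matter, though the share is not read as an amount of RNA because the spike-in dose of the IP is not given: over 6 fractions at equal depth the scale rose with the spike-in share (Pearson r = 0.867, exact permutation p = 0.0417; Spearman rho = 0.886, exact permutation p = 0.0333), with r = 0.635 without the 2 farthest fractions and the same order within 2 of the 3 lines. Both S38A fractions had the lowest shares, so this, an effect of the S38A form and other differences between the lines cannot be told apart. The permutations took the 6 fractions as independent, though each line gave 2 of them, so their p-values may be too small. The spike-in share also fell as IP gene counts before thinning rose (Pearson r = -0.956). Thinning equalizes counts only, so other properties of IP libraries that go with their original depth cannot be told apart from the share.

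Without the first WT fraction and with the fraction as a block, 366 genes were higher and 39 lower in S38D than in S38A in IP over input. A candidate explanation is a smaller change in the same direction in S38A, which predicts the sign of the change in the second WT fraction. That sign was seen in 92.8% of the called genes, in 96.2% of those higher and 61.5% of those lower, but also in 89.1% and 76.9% of uncalled genes matched to these on their S38D change, so it does not separate a smaller change in S38A from a larger one in S38D. The median log2 change was 0.40 in S38A, 0.90 in S38D and 0.60 in the second WT fraction for the higher genes, and 0.09, -0.48 and -0.08 for the lower ones, with the opposite sign in S38A. The genes were called for the gap between S38A and S38D in these same libraries, so selection set the medians of these lines apart. On a scale from 0 at S38A to 1 at S38D, the WT fraction lay at 0.26 to 0.52 for the higher genes. For the lower genes it lay at 0.31 to 0.41, each over 4 choices of fractions. A fraction outside the contrast can lie between the lines through selection alone. With 1 WT fraction both explanations and the spike-in share thus stay open.

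The log2 IP over input values of fractions from the same line correlated across genes no more than those from different lines (mean 0.537 against 0.541, exact permutation p = 0.533 over 15 pairings, where the smallest possible is 0.0667).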
